A study of Saccharomyces cerevisiae with 32 samples.

How the data were processed

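mRNA and ribosome footprint libraries were made from whole yeast cells grown in synthetic complete medium and shifted to the stated temperature, per the labels' protocols. All cultures received cycloheximide at 100 µg/ml for 2 min before harvest, and footprints were produced with RNase I, per the labels' protocols. Cycloheximide stops elongating ribosomes, so footprints show where ribosomes stood when it acted. The 32 samples form 16 groups of 2 replicates, which the series design calls biological.

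The authors deposited 4 tables, 1 for each mutant and temperature, with log2 normalized abundances per gene for footprints and mRNA of the wild type and the mutant. Each deposited column stands for a group of 2 labelled replicates, and how the replicates were combined is not given in the sources used here. The tables also hold the authors' log2 differences of mutant minus wild type for footprints, mRNA and TE. Their TE difference equalled the footprint difference minus the mRNA difference within rounding. mRNA levels were printed by the authors to 1 decimal for most columns, so the deposited differences, which carry more digits, were used for changes within a table. CASAVA 1.8, Bowtie2 2.0.6, TopHat2 2.0.7, DESeq and the genome build sacCer2 are named, per the submitters' processing notes, without their roles. The annotation, strand setting, treatment of reads that match several places and filters on low values are not given in the sources used here. Because abundances were normalized within each table, a change is relative to the other genes and says nothing of the total amount of translation.

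Low footprint values were spaced like the log2 of whole reads, and far lower values that all coincided were read as 0 reads. The value of 1 read was estimated per column from these steps, and footprint depth from the sum of all values divided by it. Among genes of up to 10 reads, the share within 0.1 read of a whole number was 73.5% and 38.0% for the wild type and ded1-cs at 15 °C, 100% for both strains of the ded1-ts table, 79.5% and 69.2% for the TIF1 strains at 30 °C, and 95.1% and 100% at 37 °C. Chance gives 20%, so the depth of ded1-cs is the least certain. The mRNA values did not allow this, and the depth of the mRNA libraries is unknown. The standard error given for a footprint change was computed from these read numbers. It covers counting error only, since reads without molecular identifiers are not independent molecules, and it leaves out differences between cultures.

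Gene symbols and coding lengths came from a reference gene table of assembly R64. Of the genes in the tables, all but 2 per table matched it by systematic name, and 96.3% of its protein-coding lengths are multiples of 3. As its assembly differs from that of the files, no coordinates are given. A gene entered when the mean of its wild-type and mutant abundance was at least 10 in both assays and no footprint value stood for 0 reads; 1 gene at 30 °C was left out for the latter reason alone. Changes of at least 2-fold were counted. The comparisons, 30 gene lists, the rule for named genes and the filter alternatives were chosen before the data were examined. Count-based tests with the replicates, with a term for genotype and assay together, had been planned, but the files hold log2 values without replicates. They were replaced by counts of changes by size, and the abundance floor, the fold threshold and the percentile rule for lists were set once the unit was known.

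Named genes were those with a standard name, an abundance of at least 100 in both assays and the largest changes: up to 10 per direction for each TE change and 5 per direction for each mRNA change, each difference between mutants and wild-type TIF1 at 37 °C against 30 °C. The 3 members with the largest changes at that abundance were named for each list that stood apart. Members called highest or lowest are thus the extremes among those of abundance 100 or more. DED1, TIF1, TIF2, GCN4 and PMA1 were always to be named; TIF1 was not analysed here. The planned rule also asked for a test and for replicates that did not overlap, which could not be applied.

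The lists were cytosolic ribosomal proteins, mitochondrial ribosomal proteins, translation initiation factors, translation elongation and termination factors, cytosolic aminoacyl-tRNA synthetases, ribosome biogenesis factors, RNA polymerase subunits, glycolysis and ethanol fermentation, the TCA cycle, nuclear-encoded oxidative phosphorylation, heat-shock chaperones, general stress response with trehalose and glycogen, amino acid biosynthesis, sulfur and methionine metabolism, ergosterol biosynthesis, proteasome subunits, vacuolar ATPase subunits, nuclear pore proteins, histones, cell wall proteins, plasma membrane transporters, ER translocation with glycosylation and vesicle transport, cell-cycle regulators, protein kinases, transcription factors, mRNAs with characterised upstream open reading frames, mating and pheromone response, auxotrophic marker genes, mRNA decay factors, and the actin and tubulin cytoskeleton. The median change of a list was placed among 10000 random lists of the same size, drawn within 10 bins of mean mRNA abundance. A list stood apart below the 1st or above the 99th percentile, as a description of these libraries. Random lists were not matched on coding length. With 30 lists, 0.6 would stand apart by chance in a comparison. The rule was tried on lists of 30 of the 4854 genes of tif1-ts at 37 °C, with simulated values in place of their TE changes. These were independent normal values of the same SD with an added abundance trend. Of such lists, 1.5% were called higher with no shift, 21.5% with a shift of 0.25 and 82.0% with a shift of 0.5. Members of real lists may share coding length or regulation, which the simulation left out.

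Overlaps between mutants were set beside the number expected for independent lists, and correlations were computed across genes. The wild-type TE against which the TE change was ranked came from another table, so that both did not share the same values. Alternatives were no filter, an abundance of at least 100, prior counts of 0.5, 2 and 5, centring on the median change, random lists matched on footprints, list means, and wild-type TIF1 mRNA of 30 °C in place of 37 °C. For correlations, spreads and trends, 200 bootstrap draws over genes gave a 95% interval. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.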

Results

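Ded1 and eIF4A are DEAD-box RNA helicases that act in translation initiation in budding yeast, and eIF4A is encoded by a pair of near-identical genes, TIF1 and TIF2. The design asked how mutations in either helicase changed the translational efficiency (TE) of mRNAs across the genome, where TE is the ribosome footprint abundance of a gene relative to its mRNA abundance. The 32 samples were 16 mRNA libraries and 16 ribosome footprint libraries, which formed 16 groups of 2 biological replicates. A cold-sensitive DED1 mutant (ded1-cs) was set against wild-type DED1 at 15 °C, and a temperature-sensitive mutant (ded1-ts) against wild-type DED1 at 37 °C. A temperature-sensitive TIF1 mutant (tif1-ts) was set against wild-type TIF1 at 30 °C and again at 37 °C. The files gave 1 value per group rather than 1 per replicate, so no difference reported here has a replicate check, and no p-values were computed across genes. All changes are log2 values of mutant over wild type, and "higher" or "lower" describes these libraries.

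The 4 tables held 4918 genes for ded1-cs, 5326 for ded1-ts and 4921 for each tif1-ts comparison, of which 4855, 5238, 4833 and 4854 were abundant enough to enter. Footprint depth, estimated from the spacing of the lowest values and was 11.95 M reads in wild-type DED1 at 15 °C and 6.30 M in ded1-cs. It was 10.39 and 9.99 M reads for wild-type DED1 and ded1-ts at 37 °C. For TIF1 it was 5.67 M in the wild type and 4.72 M in the mutant at 30 °C, and 11.82 and 3.88 M at 37 °C. The depth of the mRNA libraries is unknown.

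The mutated genes were examined first. DED1 (YOR204W) itself had more mRNA and a higher TE in ded1-cs, with changes of 0.95 and 1.09 in the authors' deposited table. In ded1-ts the DED1 mRNA change was -0.77 and the TE change 0.19 in the authors' deposited table. In the tif1-ts strain the DED1 TE change was -0.35 at 30 °C and -0.40 at 37 °C, per the authors' deposited table. TIF1 was not analysed here. TIF2 (YJL138C), whose reads cannot be told from those of TIF1 with certainty, had TE changes of 0.64 at 30 °C and 0.69 at 37 °C in tif1-ts, per the authors' deposited table. The corresponding TIF2 values in the authors' deposited table were 0.67 in ded1-cs and 0.25 in ded1-ts. PMA1 (YGL008C), the plasma membrane proton pump, had TE changes of -2.06 in ded1-cs, -1.15 in ded1-ts, 0.01 in tif1-ts at 30 °C and -0.52 at 37 °C in the authors' deposited table. GCN4 (YEL009C), the starvation-responsive transcription factor whose translation is controlled by upstream open reading frames, had values of -0.31, 2.94, -0.03 and 0.92 in the same order in the authors' deposited table.

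In ded1-cs at 15 °C, mRNAs of regulators, plasma membrane transporters and ER and secretory genes had lower TE as groups. Those of glycolysis, oxidative phosphorylation, chaperones and the proteasome had higher TE as groups. The largest decrease was that of PDE2 (YOR360C), the high-affinity cyclic AMP phosphodiesterase, with a TE change of -3.68 in the authors' deposited table. It was followed in the authors' deposited table by the ubiquitin protease cofactor BRE5 (YNR051C, -3.55), PAM1 (YDR251W, -3.53), the poly(A) polymerase PAP1 (YKR002W, -3.46) and the sterol-binding protein OSH2 (YDL019C, -3.35). The mitotic cyclin CLB2 (YPR119W, -3.15), the Pho85 cyclin CLG1 (YGL215W, -3.11), EFR3 (YMR212C, -2.99) and the phosphoinositide phosphatase INP53 (YOR109W, -2.96) were also among the lowest in the authors' deposited table. mRNA of these genes differed less, from 0.05 for EFR3 to 0.92 for BRE5 in the authors' deposited table. The highest TE changes in the authors' deposited table belonged to the alcohol dehydrogenase ADH4 (YGL256W, 2.13), the mitochondrial ribosomal protein MRP2 (YPR166C, 1.81), RTC3 (YHR087W, 1.75) and the stress protein HSP12 (YFL014W, 1.74). For RTC3 and HSP12 the TE rise came with a larger decrease of mRNA, so their footprints were lower in the mutant. The metallothionein copies CUP1-1 (YHR053C) and CUP1-2 (YHR055C) had identical entries of 1.73 in the authors' deposited table and are uncertain, since they share reads. RIB1 of riboflavin synthesis (YBL033C, 1.72), the mitophagy factor ATG44 (YIL156W-B, 1.71), the polyadenylation factor PFS2 (YNL317W, 1.69) and ADF1 (YCL058W-A, 1.63) followed in the authors' deposited table. ADF1 lies antisense to another gene, and strand use in the counting is not given in the sources used here, so its value is uncertain.

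Over all 4855 genes, 847 (17.4%) had a TE at least 2-fold lower in ded1-cs and 419 (8.63%) at least 2-fold higher. The SD of the TE change across genes was 0.96. The median change of all genes was 0.10, and relative to that median the counts were 956 lower and 278 higher. For the genes named above, the standard error of the footprint change from counting alone lay between 0.04 and 0.32.

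Of 30 gene lists, 6 stood below and 6 above the range of random lists of matched mRNA abundance in ded1-cs, where 0.6 would be expected by chance. The random lists were not matched on coding length, with which the TE change had a rho of -0.42 across genes. Protein kinases had a median TE change of -0.93, and 42 of 91 measured kinase mRNAs were at least 2-fold lower, against 1 that was at least 2-fold higher. KSP1 (-2.83), the osmotic stress kinase PBS2 (-2.42) and AKL1 (-2.33) led that list in the authors' deposited table. Cell-cycle regulators had a median of -0.71, with 17 of 48 at least 2-fold lower and none higher by that much; beside CLB2, CLB1 (-2.38) and the G1 cyclin CLN3 (-2.35) led it in the authors' deposited table. Sequence-specific transcription factors had a median of -0.53, with 44 of 116 at least 2-fold lower, among them SFP1 (-2.51), SKN7 (-2.41) and MSN2 (-2.37) in the authors' deposited table. The 20 measured mRNAs with characterised upstream open reading frames had a median of -0.80, and 8 were at least 2-fold lower, including CLN3, HEM3 (-2.08) and IMD4 (-1.48) in the authors' deposited table. Plasma membrane transporters had a median of -0.31, with 17 of 66 at least 2-fold lower, led by YOR1 (-2.65), the iron oxidase FET3 (-2.26) and PDR12 (-2.20) in the authors' deposited table. Genes of ER translocation, glycosylation and vesicle transport had a median of -0.35, with 21 of 70 at least 2-fold lower; the signal recognition particle receptor gene YDR292C (-2.89), VAN1 (-2.66) and SEC21 (-2.51) led them in the authors' deposited table.

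The lists with higher TE in ded1-cs covered energy metabolism, protein folding and turnover, the cell wall and ribosome assembly. Glycolysis and ethanol fermentation had a median of 0.77 over 17 measured genes, with ADH1 (1.28), GPM1 (1.19) and TPI1 (1.15) at its head in the authors' deposited table. Proteasome subunits had a median of 0.65, and 29 of 34 were above 0; PRE8 (1.48), SEM1 (1.38) and RPN13 (1.27) had the highest values in the authors' deposited table. Heat-shock chaperones had a median of 0.62 with 26 of 33 above 0, led by SIS1 (1.304), CPR6 (1.22) and FES1 (1.16) in the authors' deposited table. Nuclear-encoded genes of oxidative phosphorylation had a median of 0.54 with 29 of 34 above 0, and cell wall genes one of 0.54 with 32 of 46 above 0. INH1 (1.17), RIP1 (1.16) and QCR7 (1.13) led the former in the authors' deposited table, and NCW2 (1.24), CWP2 (1.17) and SPI1 (1.13) the latter. Ribosome biogenesis factors had a median of 0.39 with 90 of 120 above 0, and IPI1 (1.58), NOP13 (1.58) and TSR3 (1.45) had the highest values in the authors' deposited table. The cell wall list did not stand apart in any of 3 alternative settings. Ribosome biogenesis lay within the range of random lists matched on footprints, glycolysis within that of list means, and oxidative phosphorylation within its range at an abundance of 100 or more.

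At the mRNA level ded1-cs differed less from its wild type, with 99 genes at least 2-fold lower and 41 at least 2-fold higher. Lower mRNA was found in the authors' deposited table for NQM1 (YGR043C, -3.48), EGO4 (YNR034W-A, -3.05), the arginine synthesis gene ARG1 (YOL058W, -2.91), RTC3 (-2.88) and HSP12 (-2.51). Higher mRNA was found in the authors' deposited table for the zinc-regulated gene ZPS1 (YOL154W, 1.68), GDS1 (YOR355W, 1.55), the citrate synthase CIT2 (YCR005C, 1.33), the respiratory regulator HAP4 (YKL109W, 1.28) and GSC2 (YGR032W, 1.23). The general stress list had a median mRNA change of -1.199, with 22 of 41 genes at least 2-fold lower; after HSP12, GPD1 (-2.38) and SPI1 (-2.21) were lowest in the authors' deposited table. All 16 measured TCA cycle genes were below 0 with a median of -0.52, and LSC2 (-1.35), SDH2 (-1.11) and SDH1 (-0.98) led them in the authors' deposited table. Oxidative phosphorylation (median -0.41), proteasome (-0.40), ergosterol synthesis (-0.29), amino acid biosynthesis (-0.26) and mitochondrial ribosomal protein genes (-0.13) also lay below their random lists. Cytosolic ribosomal protein genes (0.33), cell-cycle regulators (0.25), transcription factors (0.22) and ribosome biogenesis factors (0.12) lay above theirs. The oxidative phosphorylation and proteasome lists thus had lower mRNA beside higher TE, and both changes are measured against the same mRNA values. RTC3, HSP12 and SPI1 likewise had higher TE beside a larger decrease of mRNA, so their footprints were lower.

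In ded1-ts at 37 °C, ribosome biogenesis factors, cell-cycle regulators and protein kinases had lower TE as groups, heat-shock chaperones had higher TE, and GCN4 had the highest TE change of the named genes. The lowest values in the authors' deposited table were those of RPO31 (YOR116C, -3.22), the largest subunit of RNA polymerase III, the polyamine transporter HOL1 (YNR055C, -3.17) and the ubiquitin ligase RSP5 (YER125W, -3.02). The beta-glucan synthase FKS1 (YLR342W, -2.97), the Golgi exchange factor SEC7 (YDR170C, -2.73), SBE22 (YHR103W, -2.69) and the osmosensing kinase SSK2 (YNR031C, -2.67) came next in the authors' deposited table. REG1, a regulator of protein phosphatase 1 (YDR028C, -2.61), the RNA-binding protein SSD1 (YDR293C, -2.60) and the Golgi nucleotidase GDA1 (YEL042W, -2.60) closed the group in the authors' deposited table. GCN4 footprints went from a log2 level of 8.05 in the wild type to 11.77 in ded1-ts, against mRNA levels of 12 and 12.81, which are the authors' values. The other high TE changes in the authors' deposited table were those of the urea transporter DUR3 (YHL016C, 2.28), the heat-shock protein HSP30 (YCR021C, 1.82), TLD1 (YDR275W, 1.79), STP3 (YLR375W, 1.58) and CMI7 (YIL002W-A, 1.55). The 4 copies of the cell wall asparaginase gene, ASP3-1 (YLR155C), ASP3-2 (YLR157C), ASP3-3 (YLR158C) and ASP3-4 (YLR160C), had identical entries of 2.25 in the authors' deposited table and are uncertain.

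Of 5238 genes, 243 (4.64%) had a TE at least 2-fold lower in ded1-ts and 219 (4.18%) at least 2-fold higher, with an SD across genes of 0.60. Among the 4571 genes of abundance 100 or more in both assays, 216 were lower and 79 higher. The counting error of the footprint change of the named genes was between 0.04 and 0.24.

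Heat-shock chaperones had a median TE change of 0.39 in ded1-ts, above every random list, and 30 of 34 were above 0. After HSP30, the Hsp70 genes SSA3 (1.48) and SSA4 (1.42) were highest in the authors' deposited table. Cytosolic ribosomal proteins had a median of 0.19, and RPL41A (0.93), RPS25A (0.88) and RPL43A (0.84) had the highest values in the authors' deposited table. Many of these genes exist as near-identical copies and share reads. The median mRNA change of this list was -0.50, so its higher TE stood beside lower mRNA. Ribosome biogenesis factors had a median of -0.32, and 105 of 120 were below 0; SDA1 (-1.55), RRP12 (-1.41) and the RNA helicase DBP2 (-1.39) were lowest in the authors' deposited table. mRNAs with characterised upstream open reading frames had a median of -0.32 although GCN4 belongs to them; 13 of 20 were below 0, and after HOL1 the lowest were IMD4 (-2.43) and SCH9 (-1.53) in the authors' deposited table. Cell-cycle regulators had a median of -0.17, with CLB2 (-1.29), CLN2 (-1.15) and CDC20 (-0.88) lowest in the authors' deposited table. Protein kinases had a median of -0.12, with 53 of 96 below 0; after SSK2, the protein kinase A subunit TPK2 (-1.94) and PKC1 (-1.85) were lowest in the authors' deposited table. Mitochondrial ribosomal proteins had a median of 0.01, which was low against the 0.19 of their random lists, and MRP7 (-0.78), MRPL40 (-0.66) and MRPL10 (-0.65) were lowest in the authors' deposited table. Relative to the median change of all genes, 0.08, the value of that list was below 0.

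mRNA changes in ded1-ts numbered 135 genes at least 2-fold lower and 132 at least 2-fold higher. The lowest values in the authors' deposited table were those of the cell wall mannoprotein CWP1 (YKL096W, -4.07), the mating-type endonuclease HO (YDL227C, -3.74), the G1 cyclin PCL1 (YNL289W, -3.40), TOS6 (YNL300W, -3.06) and the histone HTA2 (YBL003C, -3.06). The highest in the authors' deposited table were ECM13 (YBL043W, 3.03), the zinc transporter ZRT1 (YGL255W, 2.77), NCA3 (YJL116C, 2.62), MOH1 (YBL049W, 2.62) and the Pho85 cyclin PCL5 (YHR071W, 2.54). All 10 histone genes were at least 2-fold lower, with a median of -2.45, and HHF1 (-2.88) and HHT1 (-2.55) followed HTA2 in the authors' deposited table. Cytosolic ribosomal protein genes had a median of -0.50 with 132 of 135 below 0. Cell-cycle regulators (-0.38), cell wall genes (-0.36), cytoskeletal genes (-0.25), ER and secretory genes (-0.25) and mitochondrial ribosomal proteins (-0.23) also lay below their random lists. CLN2 (-2.31), the tubulin genes TUB1 (-1.32) and TUB2 (-1.15), and MNN1 (-0.96) were among their lowest members in the authors' deposited table. Heat-shock chaperones had a median of 0.40, with HSP26 (1.91), BTN2 (1.298) and HSP42 (1.21) highest in the authors' deposited table. Transcription factors (0.29), upstream open reading frame mRNAs (0.26), proteasome subunits (0.23), plasma membrane transporters (0.20), kinases (0.18) and the general stress list (0.17) lay above theirs. Among them, ADR1 (1.64), the proteasome regulator RPN4 (1.24) and YAP1 (1.21) were high in the authors' deposited table.

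In tif1-ts at 30 °C, few genes differed in TE, and the named genes with lower TE had diverse functions, sugar uptake and its regulation among them. The hexose transporter HXT2 (YMR011W) had a TE change of -3.76 in the authors' deposited table, made up of an mRNA change of 2.94 and a footprint change of -0.81. The glucose repressor MIG2 (YGL209W, -1.66), the glycolytic transcription factor TYE7 (YOR344C, -1.47), DLD3 (YEL071W, -1.25) and the acetaldehyde dehydrogenase ALD6 (YPL061W, -1.24) followed in the authors' deposited table. AQR1 (YNL065W, -1.22), DPI8 (YJL133C-A, -1.14), FAA3 (YIL009W, -1.09), the calmodulin-dependent kinase CMK2 (YOL016C, -1.06) and the transcription factor SUA7 (YPR086W, -1.05) were the next in the authors' deposited table. The highest values in the authors' deposited table were those of the osmosensor HKR1 (YDR420W, 1.65), the purine synthesis gene ADE17 (YMR120C, 1.64), PMP2 (YEL017C-A, 1.31), a small partner of PMA1, and the cytochrome oxidase subunit COX4 (YGL187C, 1.203). The glutamate dehydrogenase GDH2 (YDL215C, 1.06), NNR2 (YKL151C, 1.06), MCR1 (YKL150W, 1.05), the succinate dehydrogenase subunit SDH4 (YDR178W, 1.04), MIT1 (YEL007W, 1.02) and MTD1 (YKR080W, 0.99) completed the list in the authors' deposited table.

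Of 4833 genes, 55 (1.14%) had a TE at least 2-fold lower in tif1-ts at 30 °C and 113 (2.34%) at least 2-fold higher, with an SD of 0.45. Most of these were weakly expressed, since 16 lower and 11 higher genes were among the 2645 with an abundance of 100 or more in both assays. The counting error of the footprint change of the named genes was between 0.03 and 0.15.

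Cytosolic ribosomal proteins had a median TE change of 0.37 in tif1-ts at 30 °C, and 128 of 135 were above 0. RPS10A (0.72), RPS17A (0.72) and RPL14B (0.69) were highest in the authors' deposited table. The median mRNA change of this list was -0.47, so its higher TE stood beside lower mRNA. Oxidative phosphorylation had a median of 0.44 with 29 of 33 above 0, and after COX4 the highest were ATP17 (0.87) and QCR8 (0.78) in the authors' deposited table. Plasma membrane transporters had a median of -0.21, with AQR1 and the uridine permease FUI1 (-1.01) lowest after HXT2 in the authors' deposited table. Ribosome biogenesis factors had a median of -0.12 with 83 of 120 below 0, and NSR1 (-0.95), RIO1 (-0.81) and MAK16 (-0.78) were lowest in the authors' deposited table.

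mRNA was at least 2-fold lower for 50 genes and higher for 63 in tif1-ts at 30 °C. HO (-2.04), CWP1 (-1.89), the glycolytic enzyme GPM1 (YKL152C, -1.60), the G1 cyclin CLN1 (YMR199W, -1.51) and the mitochondrial carrier DIC1 (YLR348C, -1.46) were lowest in the authors' deposited table. HXT2 (2.94), MIG2 (2.64), RTS3 (YGR161C, 2.07), the hexose transporter HXT4 (YHR092C, 2.02) and SKS1 (YPL026C, 1.85) were highest in the authors' deposited table. All 17 measured genes of glycolysis and fermentation were below 0 with a median of -0.99, among them PGK1 (-1.43) and ADH1 (-1.42) in the authors' deposited table. Histones (-0.74), heat-shock chaperones (-0.65), vacuolar ATPase subunits (-0.55), cytosolic ribosomal proteins (-0.47), ergosterol synthesis (-0.35), the proteasome (-0.33), ER and secretory genes (-0.26), the general stress list (-0.24) and mitochondrial ribosomal proteins (-0.20) were below their random lists. Among their members, HSC82 (-1.43), HSP82 (-1.38), VMA3 (-0.82) and RPL8A (-0.82) were low in the authors' deposited table. Oxidative phosphorylation (0.43), plasma membrane transporters (0.21), ribosome biogenesis (0.17) and transcription factors (0.16) were above theirs, with QCR2 (0.77), DBP6 (0.70) and XBP1 (1.11) among the high members in the authors' deposited table.

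At 37 °C the TE changes of tif1-ts were broader, with lower values for ribosome biogenesis factors as a group and higher values for general stress and respiratory genes. The myosin heavy chain MYO1 (YHR023W, -2.94), the nuclear basket protein MLP1 (YKR095W, -2.68) and the topoisomerase TOP2 (YNL088W, -2.41) were lowest in the authors' deposited table. The RNA helicase DBP2 (YNL112W, -2.19), the ribosome assembly factors NOP53 (YPL146C, -2.07) and NOP14 (YDL148C, -1.80), the golgin IMH1 (YLR309C, -1.93) and the transcription elongation factor CTR9 (YOL145C, -1.89) followed in the authors' deposited table, with NCP1 (YHR042W, -1.83) and MDM20 (YOL076W, -1.82). For MYO1 the authors' deposited table gave an mRNA change of 2.55 and a footprint change of -0.39, while for DBP2 it gave 0.31 and -1.88. The highest values in the authors' deposited table were those of FMP45 (YDL222C, 2.12) and the citrate synthase CIT2 (1.77). The 4 ASP3 copies had identical entries of 1.75 in the authors' deposited table. The subtelomeric helicase genes YRF1-3 (YGR296W, 1.75), YRF1-7 (YPL283C, 1.74), YRF1-6 (YNL339C, 1.72) and YRF1-8 (YOR396W, 1.72) had near-identical values in the authors' deposited table. Both families share reads and are uncertain.

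Of 4854 genes, 155 (3.19%) had a TE at least 2-fold lower in tif1-ts at 37 °C and 256 (5.27%) at least 2-fold higher, with an SD of 0.63 and a counting error of 0.04 to 0.13 for the footprints of the named genes. Relative to the median change of all genes the counts were 191 lower and 201 higher. With the wild-type mRNA values of 30 °C in place of those of 37 °C, 2 of the 10 named genes with lower TE stayed at least 2-fold lower, and all 10 with higher TE stayed at least 2-fold higher. Apart from FMP45 and CIT2, the latter were copies of ASP3 and YRF1, which share reads and are not separate measurements. Wild-type mRNA levels of these copies at 30 °C and 37 °C were 9.3 and 9.2 for ASP3 and 11.6 and 11.7 for YRF1. The change of values could thus hardly move them.

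Cytosolic ribosomal proteins had a median TE change of 0.51 at 37 °C, with 131 of 135 above 0, and RPS28A (1.23), RPL23B (1.08) and RPL23A (1.05) were highest in the authors' deposited table. The general stress list had a median of 0.58 with 42 of 47 above 0, led by DDR2 (1.295), TRX2 (1.27) and SOL4 (1.17) in the authors' deposited table. Median mRNA changes were -0.61 for cytosolic ribosomal proteins and -0.34 for the general stress list. Their higher TE thus stood beside lower mRNA, and both changes are measured against the same mRNA values. Oxidative phosphorylation had a median of 0.52 with 32 of 33 above 0, led by COX4 (1.27), QCR6 (1.05) and COX13 (0.93) in the authors' deposited table. Ribosome biogenesis factors had a median of -0.45, and 16 of 120 were at least 2-fold lower. Their median mRNA change was 0.37. After DBP2 and NOP14, RRP12 (-1.66) was the lowest member of this list in the authors' deposited table. NOP53, named above, was not on the list. Nuclear pore proteins had a median of -0.37 with 24 of 33 below 0, where NUP170 (-0.92) and NSP1 (-0.82) followed MLP1 in the authors' deposited table. Translation initiation factors had a median of -0.34 with 19 of 25 below 0, and the poly(A)-binding protein PAB1 (-1.44), NIP1 (-0.82) and GCD11 (-0.59) were lowest in the authors' deposited table. Heat-shock chaperones had a median of -0.25 but went both ways, as 23 of 34 were below 0 while 4 were at least 2-fold higher and 2 at least 2-fold lower. CDC37 (-1.37), SSC1 (-1.06) and CPR7 (-0.75) were lowest in the authors' deposited table, whereas the 11 genes named HSP, a group chosen after the values were seen, had a median of 0.73. ER and secretory genes had a median of -0.22 and plasma membrane transporters of -0.20, with ALG11 (-0.97), SEC61 (-0.91), SEC23 (-0.91), HXT2 (-1.66), HXT3 (-1.26) and HXT4 (-1.05) lowest in the authors' deposited table. With the wild-type mRNA values of 30 °C, 5 of these 9 lists stood apart, and nuclear pore proteins, translation initiation factors, ER and secretory genes and plasma membrane transporters did not.

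**Figure D1:**
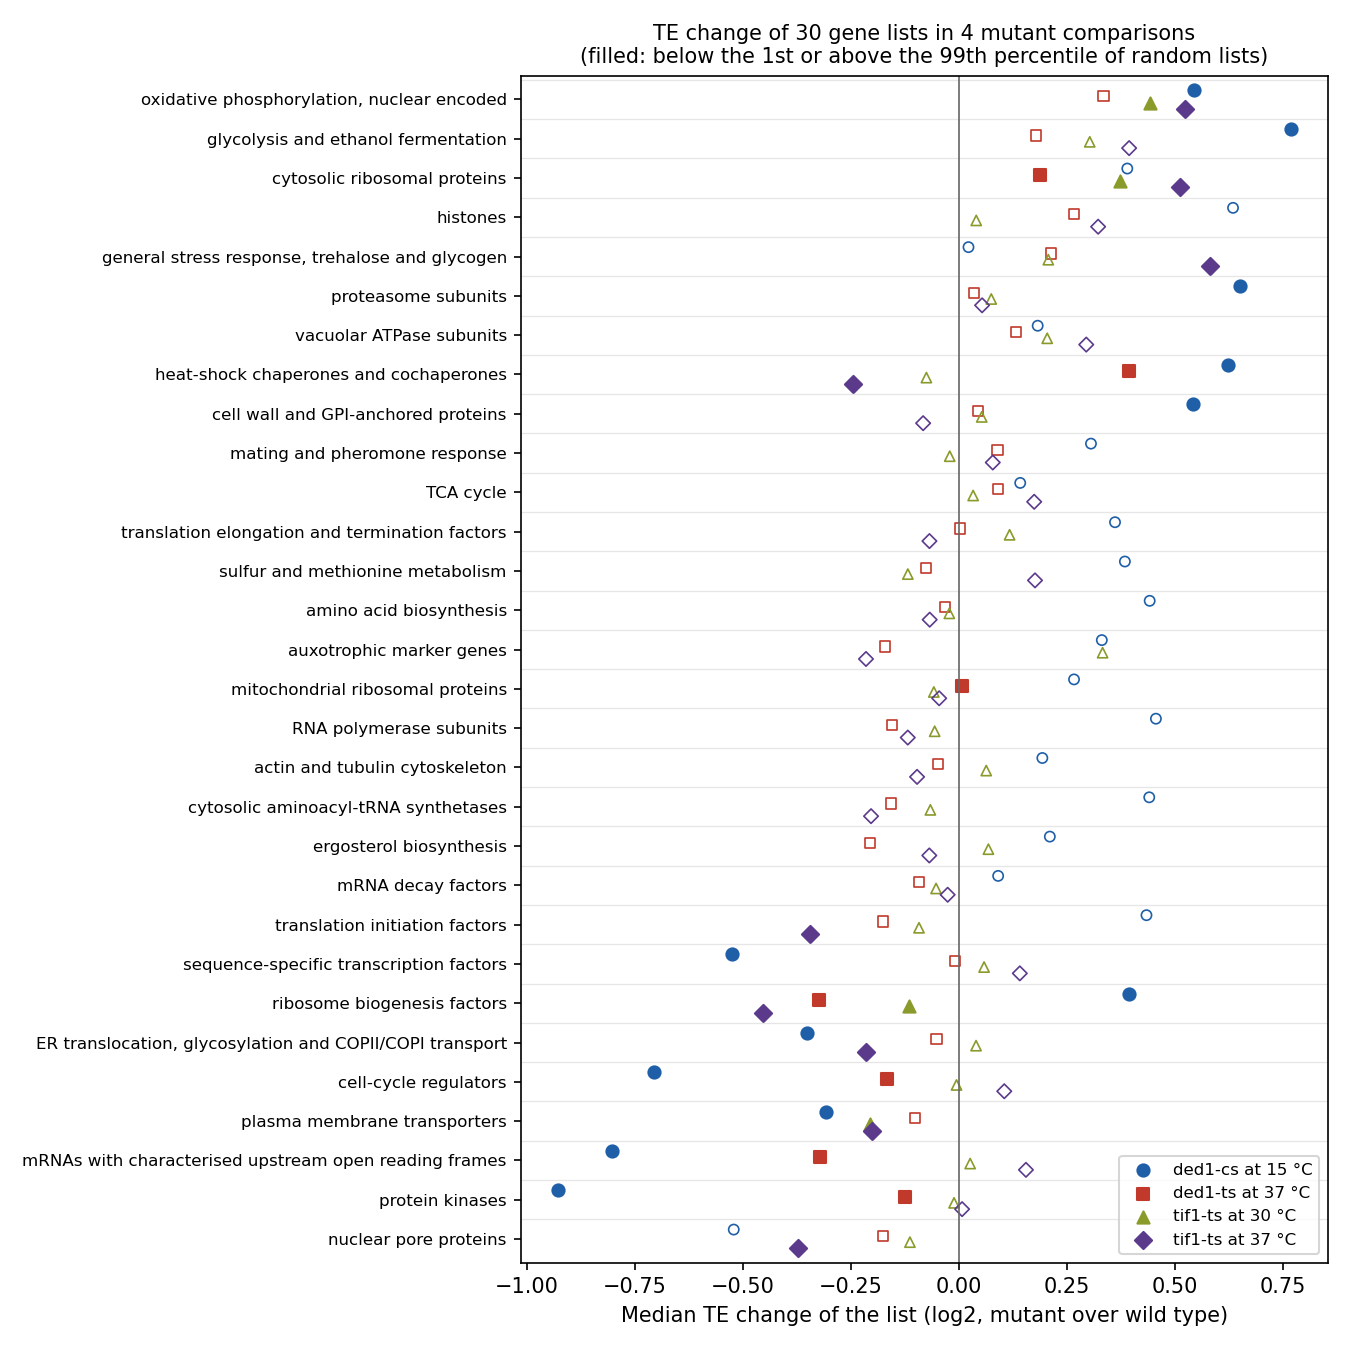
Median TE change (log2, mutant over wild type, horizontal axis) of each of 30 gene lists in the 4 mutant comparisons, with filled symbols for lists below the 1st or above the 99th percentile of 10000 random lists of matched mRNA abundance. Ribosome biogenesis factors lie at 0.39 in ded1-cs and at -0.32, -0.12 and -0.45 in the other comparisons, and protein kinases lie at -0.93 in ded1-cs.

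At the mRNA level, 157 genes were at least 2-fold lower and 184 higher in tif1-ts at 37 °C. The histone genes HTA2 (-2.93), HTB2 (YBL002W, -2.50) and HHF1 (YBR009C, -2.42), the repressor YHP1 (YDR451C, -2.27) and the cell wall protein GAS3 (YMR215W, -2.18) were lowest in the authors' deposited table. MYO1, MLP1 (2.30), NCA3 (2.05), NOP53 (2.00) and the glycine decarboxylase subunit GCV1 (YDR019C, 1.85) were highest in the authors' deposited table. All 10 histone genes were at least 2-fold lower, with a median of -1.79, and all 17 glycolysis genes were below 0 with a median of -1.02. Cytosolic ribosomal proteins (-0.61), heat-shock chaperones (-0.55), ergosterol synthesis (-0.47), cell-cycle regulators (-0.37), the proteasome (-0.35), the general stress list (-0.34) and ER and secretory genes (-0.31) were also below their random lists. HXK1 (-1.52), HSC82 (-1.50), KAR2 (-1.50), PCL1 (-2.12) and CLB1 (-1.98) were among the lowest members of these lists in the authors' deposited table. Mating genes (0.41), ribosome biogenesis (0.37), transcription factors (0.21), kinases (0.15) and plasma membrane transporters (0.14) were above theirs. The cell wall integrity kinase SLT2 (1.57), its target factor RLM1 (1.34) and PRM5 (1.47) were among the high members in the authors' deposited table. With the wild-type mRNA values of 30 °C the counts were 264 lower and 175 higher, and 10 of these 14 lists stood apart; heat-shock chaperones then had a median of 0, and they, the general stress list, ergosterol synthesis and kinases lay within the range of their random lists.

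Wild-type TIF1 cells at 37 °C and 30 °C were compared from the authors' values for each temperature, which come from tables normalized separately, so the medians were set equal first. The temperatures also come from separate sets of libraries, so a batch difference cannot be told apart from an effect of temperature. Among genes of abundance 100 or more, HSP12 mRNA was higher by 2.0 at 37 °C, followed by the peptide transporter PTR2 (1.9), RTS3 (1.8), GPM2 (1.7) and the CUP1 copies (1.7). Heat-shock chaperones had a median mRNA difference of 0.5, and the general stress list one of 0.3. Among chaperones of abundance 100 or more, AHA1 (1.7), HSP10 (1.2) and HSP82 (1.1) were highest. HSP26, just below that abundance, had a larger difference of 2.1. mRNA was lower at 37 °C for MYO1 (-2.8), MLP1 (-2.6), FMP48 (-2.0), the copper transporter CTR1 (-1.8) and ZRT1 (-1.8). Ribosome biogenesis factors had a median of -0.1, with NOP14 (-1.5), NOP7 (-1.5) and UTP14 (-1.4) lowest, and translation initiation factors one of -0.3, with NIP1 (-0.8) and FUN12 (-0.5). The former list did not stand apart at an abundance of 100 or more, nor the latter with list means, and -0.1 is the smallest step of these mRNA values. TE was higher at 37 °C for MYO1 (3.12), FMP48 (2.58), MLP1 (2.27), RTT107 (1.87) and SSA4 (1.74), and lower for DBP2 (-1.61), DUR12 (-1.51), NSR1 (-1.51), ZRT1 (-1.46) and ZRT2 (-1.37). Over 4822 genes, mRNA was at least 2-fold lower at 37 °C for 150 and higher for 72, and TE was lower for 108 and higher for 202.

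Differences between the TE changes of the mutants were then taken gene by gene. Between ded1-ts and tif1-ts at 37 °C, RSP5 (-3.12), HOL1 (-2.92), SBE22 (-2.80), RHO2 (-2.61) and SSD1 (-2.53) had lower TE changes in ded1-ts, while MYO1 (2.66), MDM20 (1.92), ERO1 (1.84), IMH1 (1.77) and SSA4 (1.68) had higher ones. The difference was at least 2-fold for 310 genes in the lower and 209 in the higher direction. Between ded1-cs and ded1-ts, the weak-acid transporter PDR12 (-3.34), GCN4 (-3.25), CLG1 (-3.08), RHO5 (-2.80) and BRE5 (-2.77) were lower in ded1-cs. HO (3.23), RPL22B (2.44), ATF2 (2.19), SAM1 (2.08) and SSD1 (2.07) were higher in ded1-cs. These counts were 731 and 335, and the contrast joins different alleles at different temperatures. Between 37 °C and 30 °C in tif1-ts, MYO1 (-3.09), MLP1 (-2.56), NOP53 (-2.14), TOP2 (-1.93) and MTD1 (-1.75) were lower at 37 °C, and CIT2 (2.81), HXT2 (2.10), DPI8 (1.90), DLD3 (1.54) and FAA3 (1.47) were higher. These counts were 188 lower and 224 higher, and 59 and 29 at an abundance of 100 or more. MYO1, MLP1, NOP53, TOP2, MDM20 and IMH1 belong to the 10 named genes of lower TE in tif1-ts at 37 °C, of which 2 stayed at least 2-fold lower with the wild-type mRNA values of 30 °C.

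**Figure D2:**
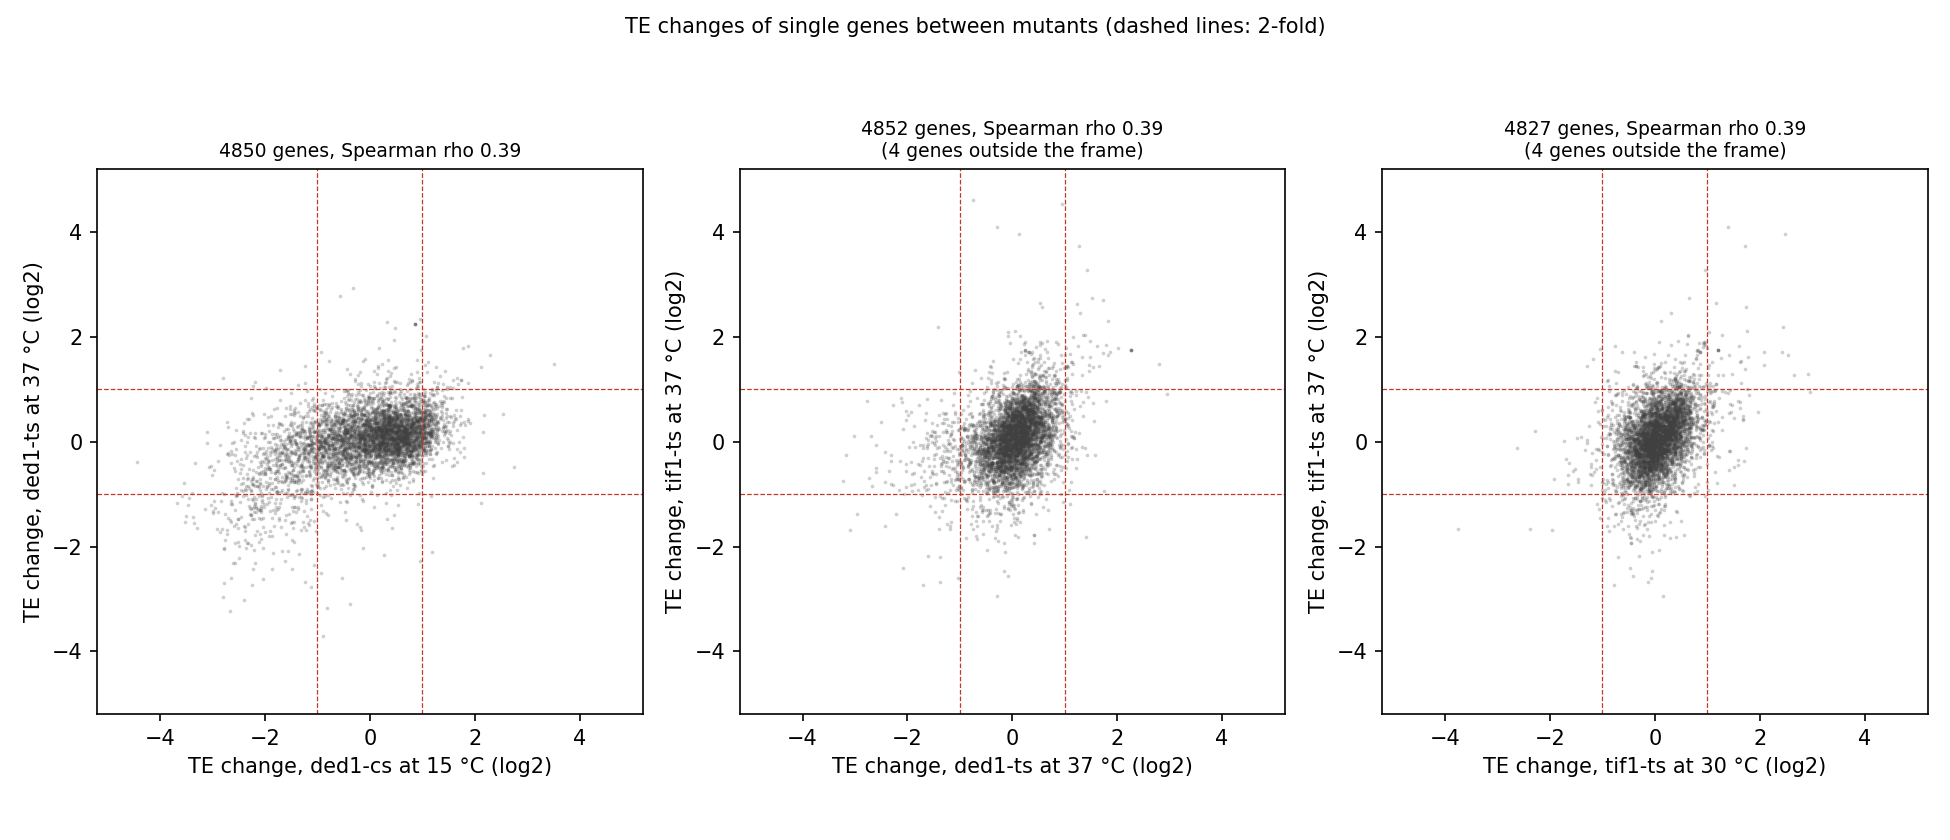
TE change (log2, mutant over wild type) of each gene in ded1-cs against ded1-ts, in ded1-ts against tif1-ts at 37 °C, and in tif1-ts at 30 °C against 37 °C, with 1 point per gene, dashed lines at 2-fold and 4 genes outside the frame of each panel that shows tif1-ts. Spearman's rho across genes is 0.39 in each panel, and 194 genes lie in the lower left corner of the first.

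Genes with lower TE were shared most between the DED1 mutants. Of 847 genes at least 2-fold lower in ded1-cs and 235 in ded1-ts, 194 were lower in both, where independent lists would share 41.0, and PMA1 and CLB2 were among them. ded1-cs and tif1-ts at 37 °C shared 50 lower genes against 27.2 for independent lists, and ded1-cs and tif1-ts at 30 °C shared 3 against 8.99. ded1-ts and tif1-ts shared 29 lower genes at 37 °C against 7.48, and 4 with tif1-ts at 30 °C against 2.65. Of genes with higher TE, ded1-ts and tif1-ts at 37 °C shared 49 against 5.86 for independent lists, ded1-cs and tif1-ts at 37 °C 64 against 19.1, and ded1-cs and ded1-ts 29 against 9.72. tif1-ts at 30 °C shared 20 higher genes with ded1-ts against 2.46, 15 with ded1-cs against 8.27 and 44 with tif1-ts at 37 °C against 5.57, beside 7 lower genes against 1.73. At an abundance of 100 or more, 137 lower genes were shared by ded1-cs and ded1-ts, where independent lists would share 25.2, and 4 higher genes against 2.08. At that abundance ded1-ts and tif1-ts at 37 °C shared 8 higher genes against 0.499 and 19 lower against 5.21, and ded1-cs and tif1-ts at 37 °C 31 against 5.41 and 29 against 13.6. tif1-ts at 30 °C then shared 0 higher genes with ded1-ts against 0.0708, 2 with ded1-cs against 0.709 and 7 with tif1-ts at 37 °C against 0.257, and 1, 0 and 3 lower genes in the same order against 1.04, 2.42 and 0.468. Across genes, the TE changes of ded1-cs and ded1-ts had a Pearson's r of 0.48 and a Spearman's rho of 0.39. The same values were 0.38 and 0.39 for ded1-ts and tif1-ts at 37 °C, 0.39 and 0.39 for tif1-ts at both temperatures, and 0.27 and 0.27 for ded1-cs and tif1-ts at 37 °C. They were 0.21 and 0.24 for ded1-ts and tif1-ts at 30 °C and 0.11 and 0.13 for ded1-cs and tif1-ts at 30 °C. Given coding length, the rho was 0.29 for ded1-cs and ded1-ts, 0.04 and 0.12 for ded1-cs and tif1-ts at 30 °C and 37 °C, 0.18 and 0.30 for ded1-ts and tif1-ts at 30 °C and 37 °C, and 0.34 for tif1-ts at both temperatures. The 4 tables share no libraries, and genes are not independent replicates.

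The spread of TE over genes widened in ded1-cs, from an SD of log2 TE of 0.87 in the wild type to 1.27 in the mutant. In ded1-ts it was 1.104 and 1.126, in tif1-ts 0.98 and 0.94 at 30 °C, and 1.05 and 0.98 at 37 °C. The decrease in tif1-ts became an increase of 0.02 at both temperatures among genes of abundance 100 or more. The TE change in ded1-cs had a Spearman's rho of 0.18 across genes with the wild-type TE of another table, taken at 37 °C, and of 0.003 with that of its own table. The corresponding values were -0.15 and -0.14 in ded1-ts, -0.07 and -0.24 in tif1-ts at 30 °C, and -0.15 and -0.28 at 37 °C, where those of the same table share the wild-type values with the TE change.

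Long coding sequences had lower TE changes in all 4 comparisons, with a Spearman's rho across genes of -0.42 in ded1-cs, -0.35 in ded1-ts, -0.21 in tif1-ts at 30 °C and -0.39 at 37 °C. In ded1-cs the shortest 10% of genes had a median TE change of 0.65 and the longest 10% one of -0.71, and their footprint changes were 0.55 and -0.56. In ded1-ts the TE medians were 0.39 and -0.24, with mRNA medians of -0.21 and 0.27. In tif1-ts they were 0.25 and -0.08 at 30 °C, and 0.44 and -0.36 at 37 °C, with mRNA medians of -0.20 and 0.16 at 30 °C and -0.29 and 0.31 at 37 °C. Without cytosolic ribosomal proteins, which have short coding sequences, the rho values were -0.41, -0.35, -0.19 and -0.38. As the random lists were not matched on coding length, this trend may contribute to lists that stood apart in any of the 4 comparisons. That was not tested.

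**Figure D3:**
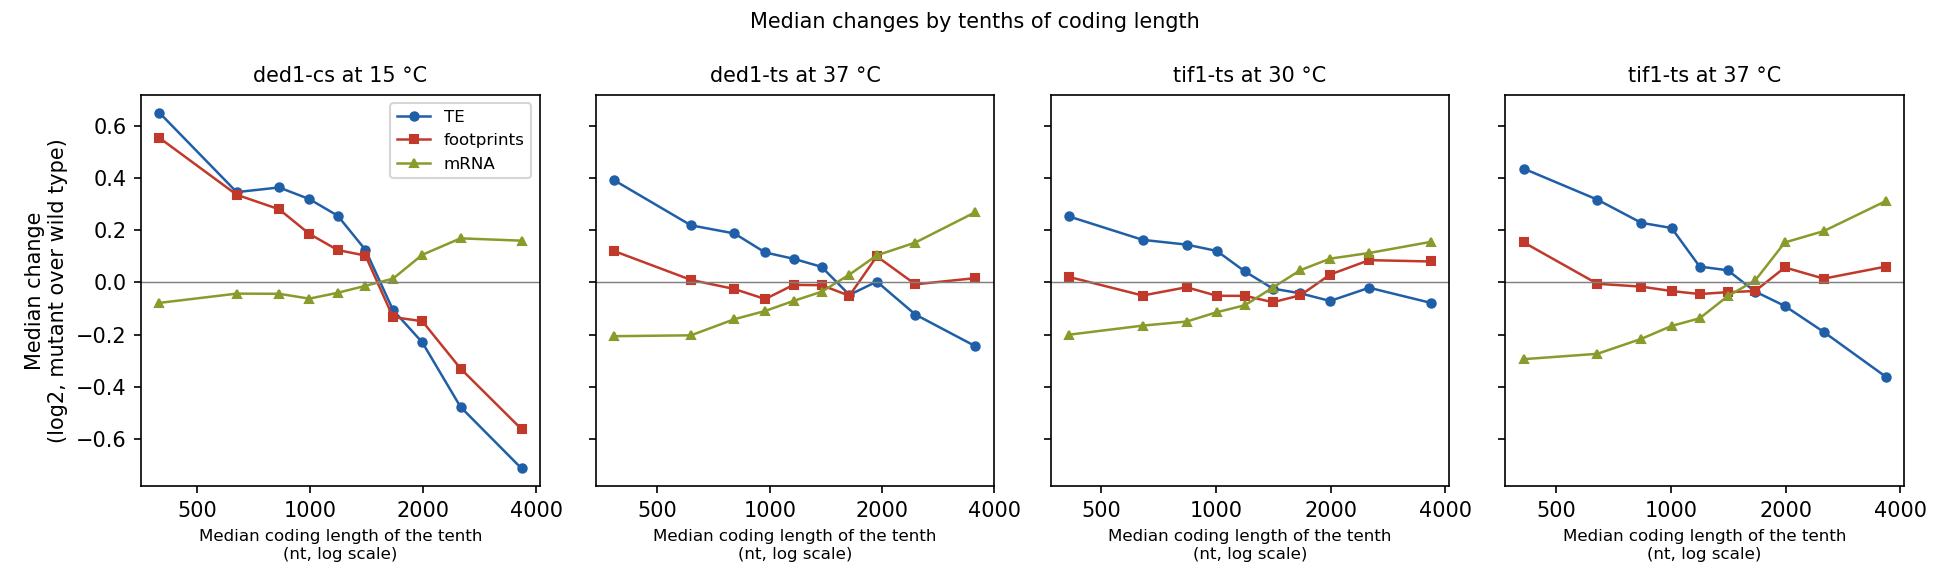
Median change (log2, mutant over wild type, vertical axis) of TE, footprints and mRNA for each 10% of genes ordered by coding length (nucleotides, log axis) in the 4 mutant comparisons. Footprint medians run from 0.55 to -0.56 in ded1-cs and vary less in the other panels, where mRNA medians go up with length.

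Of the 30 lists, 13 stood apart in TE in no mutant. Over the 4 comparisons their median TE changes ranged from 0.04 to 0.63 for histones, from 0.13 to 0.29 for vacuolar ATPase subunits, from 0.03 to 0.17 for the TCA cycle and from -0.02 to 0.31 for mating genes. The range was -0.07 to 0.36 for elongation and termination factors, -0.12 to 0.38 for sulfur and methionine metabolism, -0.07 to 0.44 for amino acid biosynthesis and -0.22 to 0.33 for auxotrophic marker genes. RNA polymerase subunits ranged from -0.16 to 0.46, aminoacyl-tRNA synthetases from -0.20 to 0.44, ergosterol synthesis from -0.21 to 0.21, mRNA decay factors from -0.09 to 0.09 and cytoskeletal genes from -0.10 to 0.19. Cytosolic ribosomal proteins lay within the range of their random lists in ded1-cs, with a median TE change of 0.39 against 0.43.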

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

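Of the tests in this part, the explanation by shallow footprint libraries and the division of the explanation by mRNA libraries into ded1-cs and the other mutants were chosen after the result was seen.

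Some gene lists and genes were noted because their TE changes went opposite ways in different mutants or at different temperatures. Ribosome biogenesis factors had a median TE change of 0.39 in ded1-cs, against -0.32 in ded1-ts and -0.12 and -0.45 in tif1-ts at 30 °C and 37 °C. The value in ded1-cs lay within the range of random lists matched on footprints. Heat-shock chaperones had medians of 0.62 in ded1-cs and 0.39 in ded1-ts, against -0.25 in tif1-ts at 37 °C. In tif1-ts at 37 °C their members went both ways, with 4 at least 2-fold higher and 2 at least 2-fold lower, and the 11 genes named HSP had a median of 0.73, so the contrast does not hold for all chaperones. CIT2 had a TE change of -1.04 in tif1-ts at 30 °C and of 1.77 at 37 °C in the authors' deposited table. DPI8 had a TE change of 1.35 in ded1-ts and of -1.14 in tif1-ts at 30 °C in the authors' deposited table. These differences were not tested, since the files hold no replicates, and ded1-cs differs from the others in temperature as well as in allele.

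TE changes were lower for longer coding sequences in all 4 mutants. Counting noise of weakly expressed genes is argued against, since at an abundance of 1000 or more the rho across genes was -0.389 or lower in every mutant, and so is dependence on abundance, with partial rho values of -0.227 or lower. A length bias of the mRNA libraries alone is argued against for ded1-cs, where length and the footprint change had a rho of -0.357. In the other 3 mutants the values such a bias needs were present, as the footprint rho was -0.0486 or higher and the mRNA rho 0.32 or higher, so a bias may account for their trend. Without cytosolic ribosomal proteins the footprint rho was -0.0628 in ded1-ts, slightly past the limit chosen for such a bias. It was 0.0680 and -0.0380 in tif1-ts at 30 °C and 37 °C. Over all 4 mutants together, with a highest footprint rho of 0.0737, that explanation stays undecided, and the effect of the helicase mutations themselves stays open and was not tested.

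In tif1-ts at 37 °C, 85 genes of abundance 100 or more had a TE at least 2-fold lower, and their mRNA change had a median of 0.76. Their footprint change had a median of -0.55, with 76 of 85 below 0. Their mRNA differed between 37 °C and 30 °C by a median of -0.8 in wild-type TIF1, against -0.1 in the mutant, with tables normalized separately, which is what low values in the wild-type mRNA libraries at 37 °C would give. Genes picked for a low TE change are prone to low wild-type mRNA at 37 °C, so the choice of genes favours this value. The choice favours a low footprint change at 37 °C as well. In tif1-ts at 30 °C, from other libraries, the TE change of these genes had a median of -0.33, with 72 of 85 below 0. Low wild-type mRNA values at 37 °C would not give that value at 30 °C. It was smaller in size than the median TE change of -1.28 at 37 °C, and the trend with coding length may contribute to it, which was not tested. The value at 30 °C was not part of the tests set beforehand. It thus does not decide how far low wild-type mRNA values account for the lower TE at 37 °C. A heat response shared by wild-type strains stays undecided. Wild-type DED1 at 37 °C differed from wild-type TIF1 at 30 °C by a median of -0.2, with 57 of 85 genes below 0, across strains and separately normalized tables. The limit set beforehand used the median alone, and by it this value goes against the explanation. The lower quartile of -0.5, which was not part of that limit, lay on the other side of it. For that reason the explanation is left undecided here. At 37 °C, wild-type DED1 was above wild-type TIF1 by a median of 0.5, with 14 of 85 genes below 0, which the choice of genes also favours. A response of the wild type to 37 °C that the mutant lacks stays open, as does an effect of the mutation on translation.

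TE changes were broader in ded1-cs than in the other mutants. At an abundance of 1000 or more, the SD of the TE change was 1.43 times the mean of the other 3 mutants. Set against that mean, counting noise of weakly expressed genes as the whole cause is argued against. The SDs at that abundance were 0.674 in ded1-cs, 0.572 in ded1-ts, and 0.332 and 0.512 in tif1-ts at 30 °C and 37 °C. The mean is thus lowered by tif1-ts at 30 °C, and against ded1-ts alone the explanation stays undecided. That floor kept 361, 665, 213 and 198 genes in the same order, so the gene sets differ. Over all genes the SD was 0.961 in ded1-cs and 0.599 in ded1-ts, a wider gap. Shallow footprint libraries stay undecided: tif1-ts at 37 °C had fewer footprint reads in total and an SD of 0.631, but ded1-cs had the lowest median per gene, with 170 reads against 187. The allele and the temperature of 15 °C cannot be separated in this design, and the depth of the mRNA libraries is unknown.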

How the results depend on the processing

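Centring on the median change, list means, random lists matched on footprints, wild-type TIF1 mRNA of 30 °C, and a prior count of 5 or centring for single genes were chosen after seeing the data.

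Of the results that answer a comparison, 158 values under alternatives were the same, 53 moved and 2 reversed, and of named genes and lists 394 were the same and 110 moved. No paired analysis was possible because the files hold 1 value per group, and for the same reason leaving out each replicate, the replicate block, the block by culture, other normalizations, another count-based test, another form of dispersion, other thresholds of the adjusted p, the inter-gene correlation and the rank-based list test were not run. Footprint depth limits weakly expressed genes, with a median of 170 to 486 reads per gene and library group.

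An abundance of at least 100 leaves fewer genes, which lowers counts. It left 2952 genes in ded1-cs, 4571 in ded1-ts, and 2645 and 2665 in tif1-ts at 30 °C and 37 °C. The median log2 wild-type mRNA level was 7.4, 8.6, 7.1 and 7.1 in the same order. The same floor is thus milder in ded1-ts, and counts at it are not on an equal footing between mutants. It gave 456 lower and 249 higher TE changes in ded1-cs, 79 higher in ded1-ts, and 16 lower and 11 higher in tif1-ts at 30 °C against 85 and 80 at 37 °C. For mRNA it gave 60 lower and 13 higher in ded1-cs, 84 higher in ded1-ts, and 17 and 82 higher in tif1-ts at 30 °C and 37 °C. Wild-type TIF1 at 37 °C against 30 °C gave 35 and 51 for TE and 74 and 22 for mRNA. Differences of TE changes were 159 lower and 69 higher for ded1-ts against tif1-ts at 37 °C, 281 lower for ded1-cs against ded1-ts, and 59 and 29 for tif1-ts at 37 °C against 30 °C. Shared genes were 4 higher for ded1-cs and ded1-ts, 0 lower and 2 higher for ded1-cs and tif1-ts at 30 °C, and 29 and 31 for ded1-cs and tif1-ts at 37 °C. They were 1 and 0 for ded1-ts and tif1-ts at 30 °C, 19 and 8 for ded1-ts and tif1-ts at 37 °C, and 3 and 7 for tif1-ts at both temperatures.

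Under the same filter, Spearman's rho between mutants was 0.468 for ded1-cs and ded1-ts, 0.210 and 0.351 for ded1-cs and tif1-ts at 30 °C and 37 °C, 0.308 and 0.459 for ded1-ts and tif1-ts at 30 °C and 37 °C, and 0.558 for tif1-ts at both temperatures. The rho with wild-type TE was 0.144 in ded1-cs, and -0.000940 and -0.0611 in tif1-ts at 30 °C and 37 °C, and the rho with coding length was -0.478, -0.350 and -0.514 in the same order. The SD of log2 TE was higher than in the wild type by 0.0846 in ded1-ts, and reversed to 0.0191 and 0.0152 in tif1-ts at 30 °C and 37 °C. The cause of these shifts was not tested.

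With no filter the SD of log2 TE differed from the wild type by 0.329 in ded1-cs, and by -0.0902 and -0.115 in tif1-ts at 30 °C and 37 °C, and with a prior count of 5 by -0.0226 and -0.0406. Centring gave 278 higher TE changes in ded1-cs, where the median change of 0.10 is subtracted. List means gave 9 lists apart in mRNA for wild-type TIF1 at 37 °C against 30 °C, where medians gave 4, and wild-type mRNA of 30 °C gave 264 lower mRNA changes in tif1-ts at 37 °C. The cause of these differences was not tested.

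Of 32 lists apart in TE, 30 stood apart at an abundance of at least 100, 28 with means and 28 with footprint-matched random lists. In ded1-cs, the cell wall list stood apart in 0 of 3 alternatives, and glycolysis, oxidative phosphorylation and ribosome biogenesis in 2 of 3. Cytosolic and mitochondrial ribosomal proteins in ded1-ts stood apart in 2 of 3. In tif1-ts at 37 °C, initiation factors stood apart in 2 of 4, and ER and secretory genes, chaperones, nuclear pore proteins and plasma membrane transporters in 3 of 4. Of 57 lists apart in mRNA, 50, 53 and 51 stood apart at an abundance of at least 100, with means and with footprint-matched lists. Those that stood apart in the fewest were the general stress list and kinases in tif1-ts at 37 °C, in 1 of 4 each, and ergosterol synthesis in tif1-ts at 30 °C, in 1 of 3. For wild-type TIF1 at 37 °C against 30 °C, ribosome biogenesis and initiation factors stood apart in 2 of 3 each.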

Other observations

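TE changes and mRNA changes went opposite ways within tables, with a rho across genes of -0.39 in ded1-cs, -0.06 in ded1-ts, and -0.27 and -0.38 in tif1-ts at 30 °C and 37 °C. As both use the same mRNA values, errors in mRNA alone may give this, and the mRNA change of each tif1-ts table was therefore set against the TE change of the other. The rho values were -0.0934 and -0.160 over 4827 genes, the weaker of which lies between what that explanation needs and what it forbids, so it stays undecided.

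Families of gene names with at least 10 members were examined after the values had been seen. Apart in TE from random lists stood 6 higher and 0 lower of 52 families in ded1-cs, 3 and 1 of 59 in ded1-ts, 5 and 0 of 53 in tif1-ts at 30 °C, and 3 and 5 of 53 at 37 °C. In ded1-cs, 11 COS genes, a subtelomeric family whose members share reads, had a median TE change of 1.18 and a median mRNA change of -0.71, and TMA (0.91), RPC (0.89), HSP (0.78), PRE (0.75) and NOP (0.67) genes were the others with higher TE. In ded1-ts, 14 THI genes of thiamine metabolism had medians of 0.49 for TE and 0.82 for mRNA, PDR (0.43) and RPL (0.23) genes were higher in TE and NOP genes lower (-0.44). In tif1-ts at 30 °C, HSP (0.49), AIM (0.44), ATP (0.38), RPS (0.37) and RPL (0.37) genes were higher. At 37 °C, HSP (0.73), RPS (0.54) and RPL (0.46) genes were higher, and NOP (-0.50), UTP (-0.50), UBP (-0.40), NUP (-0.39) and SEC (-0.38) genes lower.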
